A study of Mus musculus with 10 samples.

How the data were processed

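Total RNA of embryonic mouse testis was measured on Affymetrix Mouse430_2 arrays at 5 stages, with 2 arrays per stage. Per the labels, RNA was extracted with Trizol and labelled with biotin by a single-cycle procedure. Per the series' design text, the arrays of a stage came from independent preparations of testis, so p-values reflect the spread between preparations. How many embryos made up a preparation, their strain and whether the mesonephros was removed are not given in the sources used here. The labels refer to an earlier dataset on another array type for the methods, and that dataset was not used.

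The deposited values were 1 linear intensity per probe set and array, with no missing values over 45101 probe sets. The authors' software, its version and its scaling target are not given in the sources used here. From the values, the authors had scaled each deposited column to one level, since the mean signal without the lowest and highest 2% of probe sets was 125 on every array. The medians differed between arrays, so the columns had not been quantile normalized. The other deposited files held scanner and fluidics settings of each array, per the file headers, and were read only for the array type, the day of scanning and the fluidics module. No deposited file gives reads or counts, and the number of arrays limits the precision.

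Probe sets were named from the platform annotation, with symbols updated through Entrez gene numbers in a RefSeq gene table of assembly GRCm38.p6, which was used for names only. One gene symbol was found for 34958 probe sets, several for 932 and none for 9211. Of the named probe sets, 34754 were matched through the Entrez number, 1 through its accession, and 203 kept the platform symbol. Probe sets with several symbols named no gene. Each of 18193 genes was represented by the probe set with the highest mean log2 value over the 10 arrays, with control probe sets left out. No coordinates are given, since no genome build is named by the files.

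Values were analysed as log2(signal + 16) with limma 3.58.1 in R 4.3.3. Genes under the 40th percentile of the mean log2 value (a signal of 49.1) were left out, which left 10916 genes. One linear model with a term for stage was fitted to all 10 arrays with lmFit, and variances were moderated with eBayes and a trend on mean expression (5 residual and 8.59 prior degrees of freedom). A moderated F test asked which genes changed over the stages, and moderated contrasts compared each stage with the one before and E18.5 with E11.5. All tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05.

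A set of 28 gene lists, with 483 entries of genes that mark cell types or belong to pathways, was fixed before the data were examined, as were the model, the filter and the rule for named genes. Some genes, such as Lhx9 and Lin28a, are shared between lists and count in each. Of the entries, 435 had a probe set of their own, and the others were not analysed here. A list was tested with camera when it had at least 3 tested genes, with an inter-gene correlation preset at 0.01 and adjustment over the 28 lists of a comparison. As an alternative, camera was run with a correlation estimated from the data, and its adjusted p is given beside each list whose call it ended. That adjusted p also rose where the estimate lay below the preset. For the bipotential gonad list in E12.5 against E11.5 the estimate was 0.00473, and the adjusted p went from 0.00845 to 0.125. A call lost in this run is therefore not by itself evidence that correlation between genes exceeded the preset. The estimates themselves were well above the preset for the Sertoli cell (0.367), S phase (0.356), fibrillar matrix (0.356) and ribosomal protein (0.633) lists, among others. They lay below it for the macrophage (-0.069), smooth muscle (-0.0445) and retinoic acid (-0.0848) lists too. For lists with an estimate above the preset, the adjusted p at the preset may be too small. Counts of list members past the threshold use adjustment over all tested genes, and the counts adjusted over the list alone are given beside them.

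The genes named for a comparison were the 10 with the largest rise and the 10 with the largest fall among those past the threshold in which both arrays of one stage lay above both arrays of the other. Symbols that are clone or predicted gene names were left out of these. Up to 4 members of each list with the smallest adjusted p, a fixed panel of marker genes and the 10 genes with the smallest p in the F test were also eligible. Other called list members were named in counts of their list and followed through the alternatives, and any other gene named outside this rule is marked as chosen after its values were seen.

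The procedure was tested on simulated data made from the mean of each gene over all arrays and its moderated variance, with normal noise and 100 genes changed by a log2 of 1 and 100 by a log2 of 2 in each comparison among 10916 genes. At a log2 of 1 the genes recovered were 78 for E12.5 against E11.5, 87 for E14.5 against E12.5, 83 for E16.5 against E14.5, 76 for E18.5 against E16.5 and 87 for E18.5 against E11.5. At a log2 of 2 they were 99, 100, 100, 100 and 100 in the same order. False calls numbered 7, 12, 8, 13 and 13. A list shifted by 0.5 was found in each comparison, and of the 27 other lists 0, 0, 0, 1 and 1 were called, with noise simulated as independent between genes.

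The alternatives tried were quantile normalization, median centring, other pseudocounts, no filter and a stricter one, the mean of a gene's probe sets, exclusion of probe sets ending in _x_at or _s_at, tests of every probe set, other variance models, a minimum change of 2-fold, only the 4 arrays of the stages compared, the replicate number or the fluidics module as a block, an estimated correlation in camera, and leaving out each array in turn. Array quality weights and a fit without the E14.5 arrays were added after seeing the data, as was the comparison of E16.5 with E12.5. A term for scanning day could not be added, since each stage was scanned on a single day.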

Results

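Transcript levels were measured in embryonic mouse testis at embryonic days E11.5, E12.5, E14.5, E16.5 and E18.5, with 2 arrays per stage and 10 arrays in all. The series describes a developmental time course, and the comparisons ask which genes changed from each stage to the next and over the whole period. The period runs from about the time of sex determination, through the formation of testis cords and the appearance of fetal Leydig cells, to shortly before birth. Each value averages over all cells of a preparation. Signals are given as mean ± SD of the arrays of a stage (n = 2), and folds are on the log2(signal + 16) scale, which understates the change of genes with low signal. For Cyp17a1 in E18.5 against E11.5, for instance, the log2 change was 7.28, and 8.89 and 5.64 with pseudocounts of 1 and 64.

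Across the 10916 genes tested, the arrays of a stage correlated with r between 0.963 and 0.980, and the median absolute log2 difference between them was 0.169 to 0.252. Some arrays of different stages correlated as closely or nearly so. The r was 0.9798 between replicates 2 of E16.5 and E18.5, and 0.9583 between replicates 2 of E11.5 and E12.5. The median signal of an array was 35.2 to 57.7, with the highest value in E14.5 replicate 1. The ratio of 3' to 5' actin signal, a measure of RNA integrity, was 1.84 and 1.57 at E11.5, 1.93 and 2.03 at E12.5, 1.64 and 2.50 at E14.5, 2.60 and 2.60 at E16.5, and 1.87 and 2.62 at E18.5. The same ratio for Gapdh was 0.774 to 0.936. E14.5 was scanned on a first day, E12.5 and E16.5 on another, and E11.5 and E18.5 on the third. Scanning day and stage could therefore not be told apart in the steps between neighbouring stages, while E18.5 against E11.5 lay within a day. E11.5, E12.5 and E14.5 were washed and stained in fluidics modules 1 and 2, and E16.5 and E18.5 in modules 3 and 4. Module could therefore not be told apart from stage in E14.5 to E16.5 or in E18.5 against E11.5.

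Over the 5 stages 3783 genes changed (34.7%, moderated F test). Of these, 786 had their highest mean at E11.5, 612 at E12.5, 354 at E14.5, 1026 at E16.5 and 1005 at E18.5. The genes with the smallest p included Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, whose signal was 77.25 ± 13.4 at E11.5, 4.75 ± 0.354 at E12.5 and 3158 ± 406 at E16.5. Nfix, a nuclear factor I transcription factor, went from 4.60 ± 2.26 at E11.5 to 862 ± 14 at E18.5. Its change was 42.7-fold, but 5.71-fold with the mean of its probe sets. With a pseudocount of 1 it was 10.2-fold. The probe set was chosen anew under that setting. The signals above cannot give so small a fold, so this value belongs to another probe set. Hmga2, a chromatin protein of embryonic cells, went from 4654 ± 519 to 74.9 ± 13.2. Itih5 went from 21.15 ± 2.48 to 1961 ± 161, and Gsta2, a glutathione transferase, from 18.75 ± 7.00 to 881 ± 99.5. The change of Itih5 was 53.2-fold, and 14.6-fold with the mean of its probe sets.

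**Figure D1:**
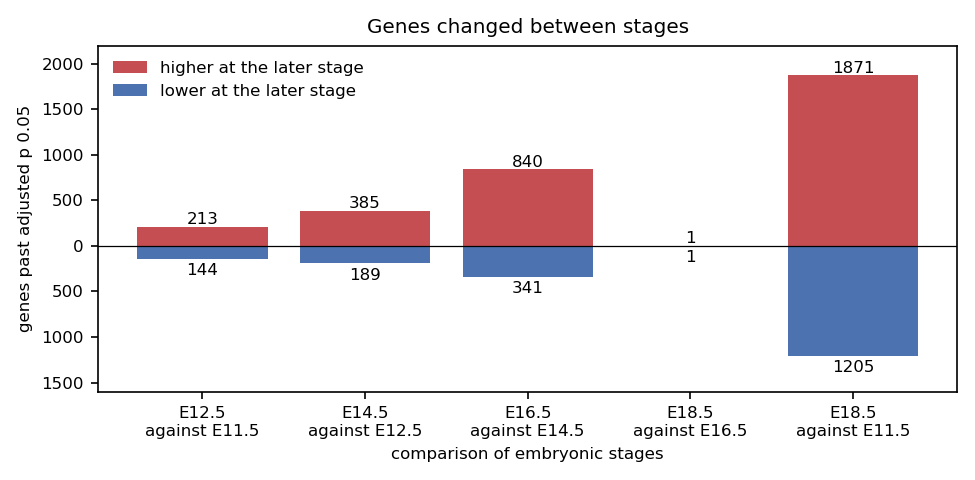
Bars give the number of genes past an adjusted p of 0.05 in each comparison of stages (n = 2 arrays per stage), with genes higher at the later stage above the line and genes lower at the later stage below it. The step from E16.5 to E18.5 had 1 gene in each direction, and E18.5 against E11.5 had 1871 above and 1205 below.

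Sertoli cell genes rose between E11.5 and E12.5. Cst9, a cystatin of fetal Sertoli cells, went from 297 ± 8.77 to 2285 ± 236 (7.33-fold, adjusted p 7.4e-07), and Ptgds, a prostaglandin D synthase, from 66.25 ± 20.3 to 897 ± 200.4 (11.1-fold, adjusted p 2.77e-05). Dhh, the hedgehog ligand made by Sertoli cells, went from 58.85 ± 4.74 to 403 ± 30.3 (5.59-fold, adjusted p 1.44e-05). Col9a3, a collagen chain, rose 13.5-fold from 18.15 ± 10.8 to 437 ± 73.5 (log2 3.76, and 2.62 with the mean of its probe sets). Of the 18 Sertoli cell genes tested, 10 rose, 0 fell and 8 did not pass (10 rose adjusted over the list alone), with a mean log2 change of 1.40 and an adjusted p of 4.93e-15 (camera), but adjusted p = 0.125 with an estimated correlation. Amh, which encodes anti-Müllerian hormone, rose from 4.75 ± 0.0707 to 106 ± 77.9 (adjusted p 0.0244), a call lost without E11.5 replicate 1, without E11.5 replicate 2 or without E12.5 replicate 2. Sox9, the Sertoli cell transcription factor, measured 199 ± 0.354 at E11.5 and 133 ± 8.77 at E12.5, which did not pass (log2 -0.53, SE 0.23, adjusted p 0.312).

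Some genes of the early gonad fell in the same step. Nr0b1, a nuclear receptor of the early gonad and adrenal, went from 295 ± 2.90 to 80.1 ± 0.283 (3.24-fold lower, adjusted p 0.000358), and Gadd45g, which acts upstream of Sry, from 580 ± 98.6 to 169 ± 80.2 (3.35-fold lower, adjusted p 0.00275). Of the 12 genes of the bipotential gonad list, 4 fell (Nr0b1, Gadd45g, Wt1 and Emx2), 0 rose and 8 did not pass (4 fell adjusted over the list alone). Leaving out 1 array ended the call of Wt1 in 6 of 10 fits and that of Emx2 in 3. The list was shifted down (median log2 -0.36, adjusted p 0.00845), and adjusted p = 0.125 with an estimated correlation. Sry, the testis-determining gene, lay below the filter and was not tested, with 136 ± 15.9 at E11.5 and 30.5 ± 18.9 at E12.5. Among the ovarian and pre-granulosa genes, Wnt4, a signal that favours ovary development, fell from 444 ± 5.45 to 180 ± 15.3 and Msx1 fell from 242 ± 57.0 to 83.05 ± 25.4 (lost in 2 fits with an array left out), while 8 of 10 did not pass and the list was not called (2 fell, or 4 fell and 1 rose adjusted over the list alone, adjusted p 0.0515). Foxl2, a granulosa cell factor, measured 108 ± 23.1 and 111 ± 14.1. Cyp11a1 fell 4.47-fold from 77.25 to 4.75 (adjusted p 5.16e-05), a call lost with the mean of its probe sets, and Cpa1, a carboxypeptidase, fell 5.53-fold from 644 ± 215 to 101 ± 19.2.

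Some germ cell genes rose from E11.5 to E12.5. Dazl, an RNA-binding protein of germ cells, went from 149 ± 65.5 to 751 ± 91.8 (4.83-fold, adjusted p 9.37e-05), and Ddx4, the germ cell helicase also called vasa, from 113 ± 50.6 to 372 ± 14.1 (3.14-fold, adjusted p 0.00234). Of the 16 prospermatogonia and piRNA genes, 5 rose (Ddx4, Dazl, Mael, Asz1 and Stk31), Tdrd9 fell and 10 did not pass (7 rose and 1 fell adjusted over the list alone). Leaving out 1 array ended the calls of Mael and Asz1 in 3 fits each, Stk31 in 5 and Tdrd9 in 7. The median log2 change was 0.48 (adjusted p 9.79e-05), and adjusted p = 0.125 with an estimated correlation. Of the 11 meiosis genes 4 rose, among them Sycp3, a synaptonemal complex protein, from 28.6 ± 10.04 to 81.05 ± 10.4, and the cohesin gene Smc1b from 10.2 ± 1.98 to 74.0 ± 0.141 (6 rose adjusted over the list alone). The call of Sycp3 was lost in 2 such fits. Their median was 0.64 (adjusted p 1.14e-06), and adjusted p = 0.125 with an estimated correlation. The pluripotency list, in which 1 of 18 genes rose (Lefty1, 2 adjusted over the list alone), was shifted up by a median of 0.28 (adjusted p 0.00338, and adjusted p = 0.211 with an estimated correlation). This list call was also lost without E12.5 replicate 1 and with the stricter filter. The call of Lefty1 was lost in 2 fits with an array left out. Pou5f1, the pluripotency factor Oct4, measured 224 ± 61.0 and 242 ± 94.6 and did not pass.

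Some matrix and interstitial genes also rose by E12.5. Col6a2, a collagen VI chain, went from 247 ± 16.8 to 877 ± 122 (3.38-fold, adjusted p 5.16e-05), and 8 of 18 fibrillar and stromal matrix genes rose with none falling (11 rose adjusted over the list alone). Their median log2 change was 0.66 (adjusted p 4.76e-12, and adjusted p = 0.125 with an estimated correlation). Ptch1 and Hhip, targets of hedgehog signalling, went from 278 ± 3.61 to 1014 ± 97.9 and from 2.70 ± 0.566 to 69.15 ± 16.1. The log2 change of Ptch1 was 1.80, and 1.03 with the mean of its probe sets. Both were among 5 of 14 interstitial genes that rose, of which Gli2 was lost in 8 fits with an array left out, Wnt5a in 5 and Cdh11 in 3, while Nr2f1 fell and 8 did not pass (7 rose and 1 fell adjusted over the list alone, median 0.50, adjusted p 0.000229, and adjusted p = 0.132 with an estimated correlation). In the smooth and peritubular muscle list, Acta2, smooth muscle actin, and Mylk rose, Myl9 fell and 6 of 9 did not pass (3 rose and 1 fell adjusted over the list alone, adjusted p 0.042, and adjusted p = 0.185 with an estimated correlation). This list call was also lost in 8 other settings, among them those without E11.5 replicate 2 or E12.5 replicate 2, and the calls of Acta2, Mylk and Myl9 were each lost without E12.5 replicate 2. The neural list, with Erbb3 rising among 3 genes (1 adjusted over the list alone), was called at 0.042, and adjusted p = 0.258 with an estimated correlation. With the mean of probe sets the neural median turned from 0.30 to -0.06 (adjusted p 0.438), and the call was also lost without a filter, with either block and without E11.5 replicate 1 or E12.5 replicate 1. The call of Erbb3 was lost in 3 fits with an array left out.

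Some lists shifted in this step with no member past the threshold over all genes. G2 and M phase genes shifted up by a median log2 of 0.39 over 23 genes (5 rose adjusted over the list alone, adjusted p 1e-05, and adjusted p = 0.258 with an estimated correlation), and S phase genes up by 0.19 over 23 (0 rose adjusted over the list alone, adjusted p 0.0373, and adjusted p = 0.597 with an estimated correlation). The S phase median turned to -0.03 without E11.5 replicate 2 (adjusted p 0.888) and was 0.06 without E12.5 replicate 1 and 0.02 without _x_at and _s_at probe sets, neither called. The G2 and M phase median was 0.13 without E11.5 replicate 2 (adjusted p 0.0576). Cholesterol synthesis genes shifted down by a median of -0.30 over 19 (4 fell adjusted over the list alone, adjusted p 2.68e-05, and adjusted p = 0.125 with an estimated correlation). Macrophage and leukocyte genes shifted down by -0.49 over 8 (4 fell adjusted over the list alone, adjusted p 0.000229, and adjusted p = 0.125 with an estimated correlation).

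In all, 357 of 10916 genes changed from E11.5 to E12.5 (limma), 213 upward and 144 downward, and 13 of 28 lists shifted, 0 of them with an estimated correlation. Fits without E11.5 replicate 1, E12.5 replicate 1 and E12.5 replicate 2 called 208, 225 and 148 genes, and a fit to the 4 arrays alone called 158. Fits with an array left out ended 2 of 10 Sertoli cell calls, 4 of 6 prospermatogonia, 3 of 4 meiosis, 3 of 6 interstitial and 5 of 8 matrix calls in at least 1 case each.

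Steroidogenic genes rose steeply between E12.5 and E14.5. Cyp17a1, the 17-hydroxylase of androgen synthesis, went from 33.55 ± 41.5 to 3326 ± 274 (83.6-fold, adjusted p 1.4e-06), Cyp11a1 from 4.75 ± 0.354 to 1239 ± 381 (59.1-fold, adjusted p 1.86e-09) and Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase, from 90.4 ± 27.7 to 2026 ± 91.0 (19.5-fold, adjusted p 6.71e-08). The E12.5 arrays of Cyp17a1 read 4.2 and 62.9, and its change was 42.3-fold without replicate 1 of that stage and 165-fold without replicate 2. The log2 change of Cyp11a1 was 5.88, and 2.36 with the mean of its probe sets. Star, which carries cholesterol into mitochondria, rose 3.12-fold from 103 ± 0.424 to 362 ± 92.1. Of the 10 fetal Leydig cell genes tested, 9 rose and 1 did not pass (9 rose adjusted over the list alone), with a median log2 change of 1.87 (adjusted p 6.77e-18), a call kept at adjusted p = 0.00824 with an estimated correlation. Of 19 cholesterol synthesis genes, 14 rose, 0 fell and 5 did not pass (17 rose adjusted over the list alone). They included Fdps, farnesyl diphosphate synthase, from 541 ± 22.7 to 1325 ± 212 (2.39-fold) and Tm7sf2, a sterol reductase, from 63.45 ± 1.77 to 195 ± 13.01 (2.65-fold), with a list median of 0.86 (adjusted p 8.97e-15, and adjusted p = 0.0158 with an estimated correlation).

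Germ cell genes of the piRNA pathway, which silences transposons, rose in the same step. Mael went from 68.85 ± 3.75 to 751 ± 172 (8.93-fold, adjusted p 8.74e-06), Gtsf1 from 34.75 ± 5.30 to 402 ± 80.2 (8.18-fold, adjusted p 4.98e-05) and Piwil4 from 3.65 ± 3.89 to 101 ± 18.53 (5.96-fold, adjusted p 0.000119). Of 16 prospermatogonia and piRNA genes, 11 rose, 0 fell and 5 did not pass (14 rose adjusted over the list alone), with a median of 1.01 (adjusted p 6.02e-15, and adjusted p = 0.0158 with an estimated correlation). Of 11 meiosis genes, 5 rose, among them Sycp2 from 33.55 ± 4.88 to 212 ± 40.9 and Sycp1 from 29.8 ± 7.92 to 168 ± 35.2 (8 rose and 1 fell adjusted over the list alone, median 0.63, adjusted p 7.55e-07, and adjusted p = 0.101 with an estimated correlation). The log2 change of Piwil4 was 2.58, and 1.57 with the mean of its probe sets. Stra8, which is needed for entry into meiosis, was not tested and measured 34.6 ± 11.6 and 67.0 ± 2.5.

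Smooth muscle genes and some matrix genes rose by E14.5. Acta2 went from 1157 ± 336 to 4424 ± 201 (3.86-fold, adjusted p 4.98e-05) and Tagln, an actin-binding protein of smooth muscle, from 129 ± 41.1 to 755 ± 34.6 (5.43-fold, adjusted p 1.74e-05). The log2 change of Acta2 was 1.95, and 1.12 with the mean of its probe sets. Of the 9 smooth and peritubular muscle genes, 7 rose and 2 did not pass (8 rose adjusted over the list alone, median 1.24, adjusted p 4.25e-10, and adjusted p = 0.015 with an estimated correlation). Of 18 fibrillar matrix genes, 8 rose and 10 did not pass, with Col6a1 from 433 ± 170 to 1714 ± 105 and Dcn, the proteoglycan decorin, from 962 ± 112 to 2504 ± 82.9 (13 rose adjusted over the list alone, median 0.66, adjusted p 8.19e-10, and adjusted p = 0.148 with an estimated correlation). The skeletal muscle list of 3 genes was shifted up, with Actc1 and Myh3, an actin and a myosin of embryonic striated muscle, rising 2.62-fold and 2.06-fold (2 rose adjusted over the list alone, adjusted p 0.0178, and adjusted p = 0.148 with an estimated correlation). Both gene calls and the list call were lost without E12.5 replicate 2 or without E14.5 replicate 1.

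DNA replication genes shifted down as a group. Rrm2, a subunit of ribonucleotide reductase, went from 2077 ± 378 to 977 ± 83.8 (2.09-fold lower, adjusted p 0.00609), a call lost without E12.5 replicate 1 or E14.5 replicate 1. Of 23 S phase genes, 7 fell and 16 did not pass (17 fell adjusted over the list alone), each of the 7 calls being lost in at least 1 fit with an array left out (Mcm7 in 7, Cdc6 in 6, Mcm5 in 5, Ccne1 in 4, Mcm4 and Ccne2 in 3), with a median of -0.63 (adjusted p 5.56e-11, and adjusted p = 0.148 with an estimated correlation). G2 and M phase genes shifted down by a median of -0.36 with none past the threshold (0 adjusted over the list alone, adjusted p 4.21e-06, and adjusted p = 0.257 with an estimated correlation). The embryonic globins Hbb-bh1 and Hba-x went from 4824 ± 279 to 308 ± 38.7 (15.0-fold lower) and from 4528 ± 168 to 955 ± 241 (4.75-fold lower), and were the 2 of 5 erythroid genes that fell (2 fell adjusted over the list alone, adjusted p 0.00656, and adjusted p = 0.25 with an estimated correlation). This list call was also lost with a pseudocount of 1. The X-linked homeobox genes Rhox6 and Rhox9 fell from 256 ± 85.1 to 15.35 ± 8.56 and from 273 ± 35.9 to 56.55 ± 12.2. In the bipotential gonad list Lhx9 alone fell (4 fell adjusted over the list alone, median -0.35, adjusted p 0.0043, and adjusted p = 0.102 with an estimated correlation), a call lost in 5 fits with an array left out. The macrophage list shifted up with none past the threshold (2 rose adjusted over the list alone, median 0.38, adjusted p 0.022, and adjusted p = 0.148 with an estimated correlation). After quantile normalization the macrophage median was 0.14 (adjusted p 0.169), and the call was also lost without a filter and without E12.5 replicate 2.

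The Sertoli cell list was not called in this step (adjusted p 0.705). Clu, the secreted chaperone clusterin, rose from 466 ± 113 to 1584 ± 519 and Defb19, a beta-defensin, from 430 ± 176 to 1399 ± 173, while 16 of 18 did not pass (3 rose and 3 fell adjusted over the list alone). The median log2 change of the list was -0.18 and its mean 0.046, so they differed in sign. Amh measured 106 ± 77.9 at E12.5 and 130 ± 113 at E14.5.

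From E12.5 to E14.5, 574 genes changed (limma), 385 upward and 189 downward (67.1% upward), and 12 of 28 lists shifted, 4 of them also with an estimated correlation. With each array centred on its median, 318 rose and 342 fell (48.2% upward), so the balance of directions depended on the scaling. Fits without E12.5 replicate 1, E12.5 replicate 2 and E14.5 replicate 1 called 183, 371 and 190 genes. Such fits ended, in at least 1 case, 1 of 9 Leydig cell calls, 8 of 14 cholesterol, 4 of 11 prospermatogonia, 1 of 5 meiosis, 2 of 7 smooth muscle and 4 of 8 matrix calls.

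**Figure D2:**
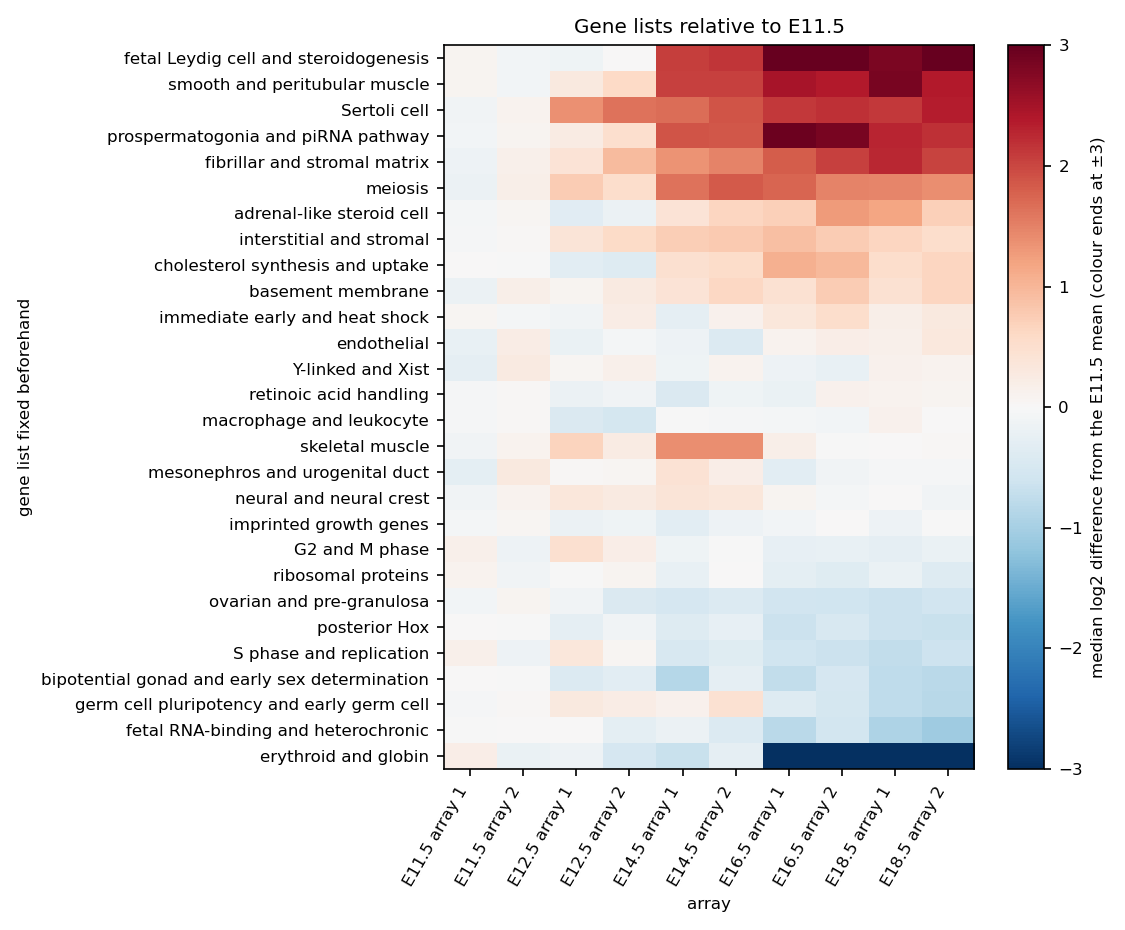
Each row is a gene list fixed before the data were examined and each column an array. The colour gives the median log2 difference of the list's tested genes from their mean at E11.5, with the colour scale ending at -3 and 3. The fetal Leydig cell list lies above 0 from E14.5 on, and the erythroid list lies beyond the end of the scale at E16.5 and E18.5.

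Pluripotency genes fell between E14.5 and E16.5. Dppa3, also called stella, went from 1878 ± 90.8 to 154 ± 65.7 (11.6-fold lower, adjusted p 5.17e-06), Dppa5a from 2468 ± 333 to 158 ± 46.9 (adjusted p 4.59e-07) and Sox2 from 154 ± 29.6 to 14.15 ± 4.17 (5.62-fold lower, adjusted p 5.15e-05). Nanog fell 3.22-fold. Of 18 pluripotency and early germ cell genes, 9 fell, 0 rose and 9 did not pass (10 fell adjusted over the list alone), with a median of -0.73 (adjusted p 2.37e-08, and adjusted p = 0.119 with an estimated correlation). Of 16 prospermatogonia genes, 6 rose, Tdrd12 fell (lost in 1 fit with an array left out) and 9 did not pass (6 rose and 2 fell adjusted over the list alone, median 0.57, adjusted p 0.00254, and adjusted p = 0.252 with an estimated correlation). The prospermatogonia call was also lost with the stricter filter and, at a median of 0.35, without _x_at and _s_at probe sets. Tdrd9 went from 50.55 ± 8.27 to 592 ± 20.9 (9.16-fold, adjusted p 8.99e-07) and Dnmt3l, a cofactor of de novo DNA methylation in germ cells, from 61.15 ± 18.3 to 359 ± 7.495 (4.92-fold, adjusted p 0.000933). Kdm1b, a histone demethylase of germ cells, rose from 131 ± 35.5 to 1001 ± 92.5.

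The steroidogenic and cholesterol lists shifted up again by E16.5. The Sertoli cell list shifted up too, after a step in which it was not called (median log2 -0.18). Its gene Dhh had been higher at E12.5 (403) than at E14.5 (246). Star went from 362 ± 92.1 to 1181 ± 102 (3.21-fold, adjusted p 0.000188), Scarb1, a lipoprotein receptor, from 827 ± 110 to 2544 ± 268 (3.04-fold) and Inha, the inhibin alpha chain, from 745 ± 146 to 2720 ± 556 (3.59-fold). Of 10 fetal Leydig cell genes, 7 rose and 3 did not pass (8 rose adjusted over the list alone, median 1.08, adjusted p 2.37e-08, and adjusted p = 0.0527 with an estimated correlation). Of 19 cholesterol genes 9 rose, led by Dhcr7, the last reductase of the pathway, from 275 ± 93.1 to 850 ± 91.3 (10 rose adjusted over the list alone, median 0.56, adjusted p 1.88e-05, and adjusted p = 0.158 with an estimated correlation). Of 18 Sertoli cell genes 6 rose, with Tesc from 302 ± 50.6 to 1003 ± 60.8 and Dhh from 246 ± 27.1 to 596 ± 45.3, Fgf9 fell (lost in 1 fit with an array left out) and 11 did not pass (9 rose and 1 fell adjusted over the list alone, median 0.74, adjusted p 0.00213, and adjusted p = 0.409 with an estimated correlation). The call of Dhh was lost with the mean of its probe sets. Cst12, a cystatin, rose 7.29-fold and Hsd17b1, a 17-beta-hydroxysteroid dehydrogenase, 4.74-fold, from 143 ± 37.8 to 736 ± 152.

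The embryonic globin Hbb-y went from 10040 ± 1845 to 215 ± 43.7 (43.6-fold lower, adjusted p 4.59e-07, and 106-fold without _x_at and _s_at probe sets), and Hba-x and Hbb-bh1 fell 18.1-fold and 7.85-fold (12.1-fold for Hbb-bh1 with the mean of its probe sets). Alas2, the heme synthesis enzyme of red cells, rose 2.47-fold from 229 ± 49.3 to 584 ± 10.4. The erythroid list was shifted down with 3 of 5 genes falling and 1 rising (3 fell and 1 rose adjusted over the list alone, median -2.97, adjusted p 0.000144, and adjusted p = 0.169 with an estimated correlation). Endothelial genes were shifted up, with Sox18 from 58.2 ± 2.83 to 174 ± 4.17 and 5 of 16 rising (10 rose and 1 fell adjusted over the list alone, median 0.63, adjusted p 0.00543, and adjusted p = 0.409 with an estimated correlation). The endothelial call was also lost with the stricter filter and without E14.5 replicate 2. Of 18 matrix genes, Eln, Mfap4 and Ogn rose (6 rose adjusted over the list alone, median 0.48, adjusted p 0.00114, and adjusted p = 0.409 with an estimated correlation), all 3 calls being lost without E14.5 replicate 1 or without E16.5 replicate 2. In the basement membrane list, not called (adjusted p 0.0959), 4 genes rose, 2 fell and 10 did not pass (5 rose and 2 fell adjusted over the list alone).

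Immediate early and heat shock genes were shifted up at E16.5, with Egr1 from 158 ± 15.4 to 597 ± 180.0 (3.46-fold, adjusted p 0.00154) and 4 of 11 rising (5 rose adjusted over the list alone, median 0.28, adjusted p 0.00543, and adjusted p = 0.409 with an estimated correlation). The actin 3' to 5' ratio in this step was 1.64 and 2.50 at E14.5 and 2.60 and 2.60 at E16.5. Hmga2 fell from 1225 ± 50.7 to 158 ± 26.0 (7.18-fold lower, adjusted p 1.23e-06, log2 -2.84 against -3.98 without _x_at and _s_at probe sets), as did Lin28a (lost in 1 fit with an array left out) and Igf2bp1 (lost in 6) among 7 fetal RNA-binding and heterochronic genes (3 fell adjusted over the list alone, median -0.40, adjusted p 0.00255, and adjusted p = 0.169 with an estimated correlation). Of 17 ribosomal protein genes Rpl11 and Rps3 fell, calls lost in 8 and 6 fits with an array left out (2 fell adjusted over the list alone, median -0.26, adjusted p 0.000156, and adjusted p = 0.409 with an estimated correlation), and this list was not called after quantile normalization. Actc1 and Myh3 of the skeletal muscle list fell 2.65-fold and 1.81-fold, calls lost in 2 and 6 such fits (3 fell adjusted over the list alone, adjusted p 0.00543, and adjusted p = 0.169 with an estimated correlation). S phase genes shifted by a median of -0.11 with none past the threshold (0 adjusted over the list alone, adjusted p 0.0263, and adjusted p = 0.558 with an estimated correlation), and G2 and M phase genes by -0.17 with Ttk alone falling, a call lost in 3 such fits (1 fell adjusted over the list alone, adjusted p 0.00998, and adjusted p = 0.49 with an estimated correlation). The S phase call was also lost without a filter, without E14.5 replicate 2 (median -0.06) and without E16.5 replicate 2.

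From E14.5 to E16.5, 1181 genes changed (limma), 840 upward and 341 downward (71.1% upward), and 14 of 28 lists shifted, 0 of them with an estimated correlation. Median centring gave 619 upward and 464 downward (57.2% upward). Fits without E14.5 replicate 1, E16.5 replicate 1 and E16.5 replicate 2 called 353, 506 and 168 genes. Other probe sets of Ptch1, Igf1, Pdgfra, Rian, Mtm1 and Hsd17b7 went in the opposite direction to the one used, so the calls of these genes in this step are uncertain. Such fits ended, in at least 1 case, 3 of 7 Leydig cell calls, 8 of 9 cholesterol, 5 of 7 Sertoli cell, 5 of 9 pluripotency, 3 of 7 prospermatogonia, 4 of 5 endothelial, 3 of 4 heat shock and immediate early and all 6 basement membrane calls.

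Between E16.5 and E18.5 only Cst12 and Alas2 passed the threshold. Cst12 rose from 948 ± 239 to 2803 ± 569 (2.94-fold, adjusted p 0.0249) and Alas2 fell from 584 ± 10.4 to 209 ± 19.9 (2.67-fold lower, adjusted p 0.0249). Both calls were lost without a filter, without a variance trend, in a fit without the E14.5 arrays and in several fits with 1 array left out, among them those without E14.5 replicate 1, E16.5 replicate 1 or E18.5 replicate 2. At an unadjusted p under 0.05 there were 538 genes, against 546 expected by chance among 10916 if none changed.

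Several lists shifted together in this step although, apart from Alas2 in the erythroid list, none of their members passed singly. Prospermatogonia and piRNA genes shifted down by a median log2 of -0.60 over 16 genes (9 fell adjusted over the list alone, adjusted p 2.16e-12, and adjusted p = 0.0415 with an estimated correlation), with Dnmt3l at 359 ± 7.495 and 199.6 ± 43.8. Cholesterol genes shifted down by -0.46 over 19 (9 fell adjusted over the list alone, adjusted p 4.78e-16, and adjusted p = 0.0413 with an estimated correlation). The erythroid list shifted down by -1.33 over 5 (4 fell adjusted over the list alone, adjusted p 2.16e-12, and adjusted p = 0.0415 with an estimated correlation). Pluripotency genes shifted down by -0.28 over 18 (3 fell adjusted over the list alone, adjusted p 3.78e-05, and adjusted p = 0.128 with an estimated correlation), and fetal RNA-binding genes by -0.31 over 7 (2 fell adjusted over the list alone, adjusted p 0.0015, and adjusted p = 0.128 with an estimated correlation). Leydig cell genes shifted down by -0.27 over 10 (1 rose and 3 fell adjusted over the list alone, adjusted p 0.0389, and adjusted p = 0.225 with an estimated correlation), with Star at 1181 ± 102 and 676 ± 63.3 and Cyp17a1 at 6156 ± 435 and 3470 ± 554. The Leydig call was also lost with a pseudocount of 1, with the mean of probe sets (median -0.14), with the replicate block and without E16.5 replicate 1, E16.5 replicate 2 or E18.5 replicate 2, and the fetal RNA-binding call with the mean of probe sets (-0.17).

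Smaller shifts were found in 5 other lists. Matrix genes shifted up by 0.18 over 18 (1 rose adjusted over the list alone, adjusted p 0.00191, and adjusted p = 0.532 with an estimated correlation), macrophage genes up by 0.16 over 8 (0 adjusted over the list alone, adjusted p 0.0115, and adjusted p = 0.128 with an estimated correlation) and Sertoli cell genes up by 0.20 over 18 (0 adjusted over the list alone, adjusted p 0.0134, and adjusted p = 0.637 with an estimated correlation). S phase genes shifted down by -0.12 over 23 (0 adjusted over the list alone, adjusted p 0.0452, and adjusted p = 0.72 with an estimated correlation) and meiosis genes by -0.14 over 11 (0 adjusted over the list alone, adjusted p 0.0474, and adjusted p = 0.501 with an estimated correlation). These 5 calls were also lost in fits with an array left out. The Sertoli median was 0.002 without E18.5 replicate 2 (adjusted p 0.783), and that call was lost too without E16.5 replicate 1 and with the mean of probe sets. The S phase median was -0.03 without E18.5 replicate 1 (adjusted p 0.511), with the call lost in 7 other settings besides, and the matrix median was 0.05 without E16.5 replicate 1 (adjusted p 0.0831). The macrophage call was lost without E16.5 replicate 2 or E18.5 replicate 1. The meiosis call was lost in 15 settings besides the estimated correlation. In all 11 of 28 lists shifted, 3 of them also with an estimated correlation, and 6 without E16.5 replicate 1.

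Over the whole period, E18.5 against E11.5, fetal Leydig cell, Sertoli cell, smooth muscle and matrix genes rose. Cyp17a1 went from 6.25 ± 0.212 to 3470 ± 554 (156-fold, adjusted p 2.74e-08), Hsd3b1 from 57.9 ± 15.6 to 3360 ± 433 (46.0-fold, adjusted p 6.49e-10) and Hao2, a hydroxyacid oxidase, from 6.15 ± 6.29 to 1507 ± 275 (69.6-fold, adjusted p 6.49e-10). The change of Hao2 was 267-fold with a pseudocount of 1 and 22.3-fold with 64. All 10 fetal Leydig cell genes rose (10 rose adjusted over the list alone, median 2.88, adjusted p 4.57e-14, and adjusted p = 0.0154 with an estimated correlation). Of 18 Sertoli cell genes 14 rose, with Defb19 from 67.7 ± 18.7 to 2761 ± 89.0 (33.6-fold) and Clu from 175 ± 10.8 to 4217 ± 1034 (21.8-fold), Fgf9 fell and 3 did not pass (15 rose and 2 fell adjusted over the list alone, median 2.24, adjusted p 4.03e-10, and adjusted p = 0.108 with an estimated correlation). Of 9 smooth muscle genes 6 rose, Acta2 8.58-fold, a log2 of 3.10 against 1.44 with the mean of its probe sets (7 rose adjusted over the list alone, median 2.61, adjusted p 5.22e-07, and adjusted p = 0.0375 with an estimated correlation). Of 18 matrix genes 16 rose, with Ogn from 10.75 ± 9.83 to 1684 ± 356 and Mfap4 from 19.1 ± 20.6 to 1729 ± 404 (17 rose adjusted over the list alone, median 2.15, adjusted p 1.63e-14, and adjusted p = 0.0782 with an estimated correlation).

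Interstitial genes rose in 8 of 14 cases and fell in 2, with Ptch1 5.42-fold higher (log2 2.44, and 1.57 with the mean of its probe sets) and Nr2f1 5.27-fold lower (10 rose and 2 fell adjusted over the list alone, median 0.57, adjusted p 0.00385, and adjusted p = 0.181 with an estimated correlation). Of 16 basement membrane genes 7 rose, with Nid1, the laminin-binding protein nidogen, from 477 ± 97.2 to 1527 ± 179.8 (7 rose adjusted over the list alone, median 0.52, adjusted p 0.00367, and adjusted p = 0.46 with an estimated correlation). The log2 change of Nid1 was 1.65, and 0.81 with the mean of its probe sets. Of 19 cholesterol genes 12 rose (13 adjusted over the list alone, median 0.59, adjusted p 0.000134, and adjusted p = 0.0782 with an estimated correlation). Endothelial genes went both ways, with 4 rising, Plvap and Emcn falling and 10 not passing (5 rose and 2 fell adjusted over the list alone), and the list was not called (adjusted p 0.685). In the macrophage list Lyz2, a lysozyme, alone rose, 1.97-fold (1 adjusted over the list alone, adjusted p 0.685).

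Germ cell genes moved in both directions over the period. Mael rose from 18.6 ± 13.4 to 1297 ± 189 (39.3-fold, adjusted p 5.04e-09), and 13 of 16 prospermatogonia genes rose (13 adjusted over the list alone, median 2.26, adjusted p 4.03e-10, and adjusted p = 0.0536 with an estimated correlation). Of 11 meiosis genes 8 rose and Syce2 fell (lost in 3 fits with an array left out), with Sycp3 5.62-fold higher (8 rose and 1 fell adjusted over the list alone, median 1.42, adjusted p 2e-05, and adjusted p = 0.0782 with an estimated correlation). Of 18 pluripotency genes 9 fell, among them Pou5f1 from 224 ± 61.0 to 69.2 ± 14.4 (2.79-fold lower, adjusted p 0.000534), and Alpl rose, a call lost in 1 fit with an array left out (10 fell and 2 rose adjusted over the list alone, median -0.83, adjusted p 3.11e-05, and adjusted p = 0.0782 with an estimated correlation). Dppa5a fell 20.3-fold.

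**Figure D3:**
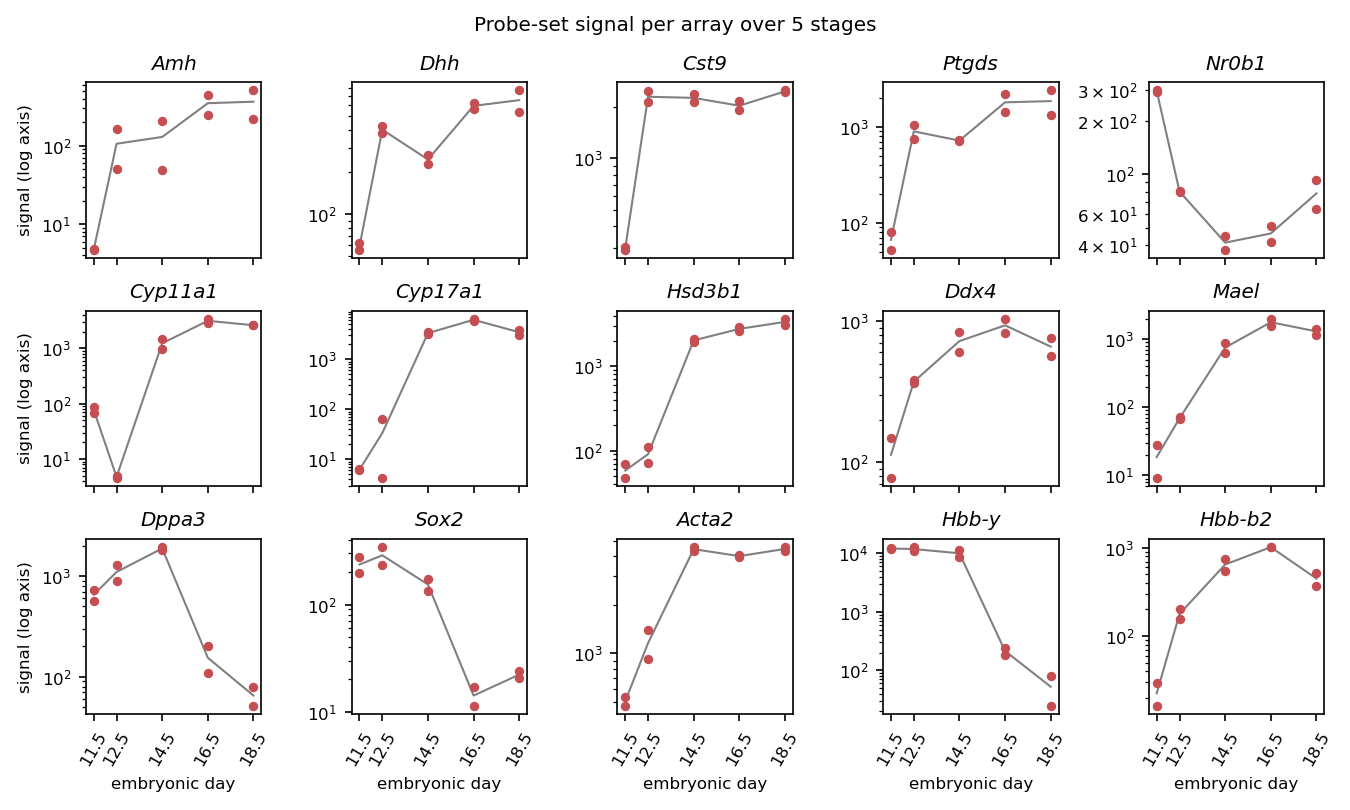
Signal of the probe set used for each of 15 genes on a log axis against embryonic day. Points are single arrays (n = 2 per stage) and lines join the stage means. Cyp17a1 lies between 3326 and 6156 as a stage mean from E14.5 on, and Hbb-y drops from 10040 at E14.5 to 215 at E16.5.

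Early gonad and S phase genes fell from E11.5 to E18.5. Emx2, a homeobox gene of the urogenital ridge, went from 1347 ± 329.8 to 97.7 ± 6.79 (11.8-fold lower, adjusted p 2.99e-08), and 6 of 12 bipotential gonad genes fell (6 adjusted over the list alone, median -0.74, adjusted p 7.85e-05, and adjusted p = 0.0538 with an estimated correlation). Of 10 ovarian and pre-granulosa genes 4 fell, Wnt4 2.90-fold and Rspo1 2.38-fold (4 adjusted over the list alone, median -0.54, adjusted p 0.000909, and adjusted p = 0.0782 with an estimated correlation). Of 23 S phase genes 17 fell, with Ccne1, cyclin E1, from 233 ± 17.3 to 52.1 ± 12.3 (18 fell and 1 rose adjusted over the list alone, median -0.70, adjusted p 1.16e-07, and adjusted p = 0.182 with an estimated correlation). Of 23 G2 and M phase genes 18 did not pass and 5 fell, each call being lost with an array left out (Top2a and Aurka in 3 fits, Birc5, Ccnb2 and Kif20a in 2) (5 adjusted over the list alone, median -0.25, adjusted p 0.0267, and adjusted p = 0.534 with an estimated correlation). This call was also lost after quantile normalization (median -0.15, adjusted p 0.101), with the stricter filter, without E11.5 replicate 1 (-0.08, adjusted p 0.293) and without E18.5 replicate 1. The embryonic globins Hbb-bh1, Hba-x and Hbb-y fell 233-fold, 229-fold and 195-fold, and with Slc4a1 made up the 4 of 5 erythroid genes that fell (4 adjusted over the list alone, median -7.60, adjusted p 1.78e-06, and adjusted p = 0.0782 with an estimated correlation). For Hbb-bh1 and Hba-x, with E18.5 signals of 14.3 and 15.3, the folds were 593 and 568 with a pseudocount of 1 and 85.9 and 85.7 with 64. Hbb-b2, an adult-type globin outside the list and chosen after its values were seen, rose from 22.4 to 448.8 (log2 3.6, limma, adjusted p 5.95e-08). The log2 change of Hbb-y was -7.60, and -8.24 and -6.97 without E18.5 replicates 1 and 2 and -8.69 without _x_at and _s_at probe sets. Rpl11 and Rps3 fell among 17 ribosomal protein genes, calls lost in 3 and 5 fits with an array left out (0 adjusted over the list alone, median -0.28, adjusted p 0.0012, and adjusted p = 0.469 with an estimated correlation), with the list not called after quantile normalization.

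Between E11.5 and E18.5, 3076 genes changed (limma), 1871 upward and 1205 downward (60.8% upward), and 18 of 28 lists shifted, 2 of them also with an estimated correlation. Median centring moved log2 changes by -0.11 and gave 1506 upward and 1775 downward (45.9% upward). The 4 arrays alone, all scanned on one day, gave 2559 genes and 18 lists. Fits without E11.5 replicate 1, E18.5 replicate 1 and E18.5 replicate 2 called 1961, 1991 and 1943. E16.5 against E12.5, the other pair within a day and chosen after seeing the data, gave 2954 genes in the fit to all 10 arrays. A fit to its own 4 arrays gave 3745. Of the 1848 genes called in both within-day comparisons, which share no array, 1840 went the same way. In both, 1210 rose and 630 fell, against 315 and 123 for independent lists. These calls came from 1 fit to all 10 arrays and share each gene's variance estimate. The 2 lists are therefore not independent, and 315 and 123 are only a rough reference. Both comparisons set modules 3 and 4 against modules 1 and 2, so the overlap is not free of a difference between modules. Other probe sets of Sparc, Grhl2, Hsd17b7 and Top2a went in the opposite direction in E18.5 against E11.5, so their calls are uncertain. Fits with an array left out ended, in at least 1 case, 0 of 10 Leydig cell calls, 3 of 15 Sertoli cell, 1 of 16 matrix, 1 of 7 basement membrane, 3 of 10 interstitial, 7 of 12 cholesterol, 2 of 6 endothelial, 2 of 13 prospermatogonia, 2 of 10 pluripotency and 12 of 17 S phase calls.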

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

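Array quality weights and the fit without the E14.5 arrays were chosen after seeing the data, and the other alternatives beforehand. Over 484 results for single genes, 10804 values under the alternatives kept their direction and side of the threshold, 855 fell short of it, 38 came to pass it and 19 turned. Over 68 results for lists the numbers were 1600, 134, 0 and 2. Those 2, in E11.5 to E12.5, were the S phase list, with medians of 0.345 and -0.0286 without E11.5 replicates 1 and 2, and the neural list, with -0.058 for the mean of probe sets. Arrays limit what can be seen at low signal, and the filter lay at a signal of 49.1.

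The count for E16.5 to E18.5, 2 genes, was 13 with a pseudocount of 64, 0 without a filter, 5 with the filter at the 60th percentile, 4 with the mean of probe sets, 5 without _x_at and _s_at probe sets, 0 without a variance trend, 4 with robust moderation, 16 with the fluidics module as a block, 1 with every probe set tested, 5 with the 4 arrays alone, 19 with array weights and 0 without the E14.5 arrays. The array weights came out equal for both arrays of a stage, so they weight stages. With the filter at the 60th percentile, which tests fewer genes, E12.5 to E14.5 gave 365. With the fluidics module as a block the counts of the first 3 steps were 566, 1003 and 1951. In the last of these the stages shared no module, so the block removed differences between modules within a stage but could not separate module from stage. Requiring at least a 2-fold change gave 216, 272 and 388 for these steps and 1180 for E18.5 against E11.5. The 4 arrays alone gave 158 for E11.5 to E12.5. With every probe set tested, 6064 changed over the stages and 5380 in E18.5 against E11.5, since genes then count more than once. The lists shifted from E16.5 to E18.5 numbered 7 with the mean of probe sets, and with an estimated correlation the lists of the 5 comparisons numbered 0, 4, 0, 3 and 2. Other causes were not tested.

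The labels name nothing that same-numbered replicates shared. Their deviations from the stage means correlated above 0 in all 10 pairs of stages (0.00444 to 0.366) and above 0.1 in 6, so some deviation was shared, but not in every pair, and the numbers were not taken to pair the samples. Within a stage the replicate number goes with the fluidics module, and the correlation was 0.363 between E11.5 and E12.5 and 0.366 between E16.5 and E18.5, which shared modules, but 0.0445 between E11.5 and E14.5, which shared them too. It was 0.157 between E12.5 and E14.5, which also shared modules. Pairs without a shared module ranged from 0.00444 (E11.5 and E18.5) to 0.172 (E14.5 and E18.5). With a replicate block the counts rose to 511, 898, 1783 and 4 for the successive steps and 3564 for E18.5 against E11.5, and an effect shared through number or module is not excluded.

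Leaving out 1 array leaves a stage with a single array, which is assumed to vary like the others. The genes changed over the stages then numbered 2717 to 4146, those of the successive steps 148 to 368, 183 to 838, 168 to 1436 and 0 to 4, and those of E18.5 against E11.5 1943 to 3291. The lists numbered 11 to 15, 11 to 14, 12 to 16, 6 to 11 and 17 to 18.

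Among the values that turned, Ptch1 in E14.5 to E16.5 was the one called, at a log2 of -0.22 with the mean of probe sets. With the mean of probe sets Sox9 in the same step was at -0.0943 and Dhh in E16.5 to E18.5 at -0.164. With quantile normalization Amh and Igf2 in E12.5 to E14.5 were at -0.117 and 0.286. In E11.5 to E12.5, Foxl2 was at -0.156 and 0.224 without E11.5 replicates 1 and 2 and at -0.0797 without E12.5 replicate 2, Pou5f1 at -0.18 without E11.5 replicate 2 and at -0.30 and 0.465 without E12.5 replicates 1 and 2, and Cyp17a1 at 1.83 and -0.139 without E12.5 replicates 1 and 2. In E12.5 to E14.5, Amh was at -0.546 without E12.5 replicate 1 and at 1.05 and -0.739 without E14.5 replicates 1 and 2. Pou5f1 was at 0.229 and -0.535 without E12.5 replicates 1 and 2, and Igf2 at -0.13 and 0.0843 without the same arrays and at 0.0736 without E14.5 replicate 1. In E16.5 to E18.5, Amh was at -0.40 without E16.5 replicate 1 and at 0.576 and -0.556 without E18.5 replicates 1 and 2, where Dhh was at 0.359 and -0.132 and Sox9 at 0.605 and -0.0327. The cause was not tested.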

Other observations

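Imprinted growth genes went both ways from E11.5 to E18.5. Dlk1, a Notch-like membrane protein, rose from 1086 ± 221 to 4534 ± 674 (4.15-fold, adjusted p 5.48e-05, log2 2.05 against 1.24 with the mean of its probe sets), and Meg3, Ndn and Plagl1 rose too. The 6 that fell were Cdkn1c, a cyclin-dependent kinase inhibitor, from 2267 ± 215 to 494 ± 15.9 (4.46-fold lower, adjusted p 1.23e-06), Peg3 from 6200 ± 419 to 2649 ± 75.9, Asb4 from 720 ± 88.8 to 39.15 ± 2.48, Igf2, a fetal growth factor, from 4835 ± 316 to 2436 ± 45.8, and Mest and Slc38a4. Of 14 genes 4 rose, 6 fell and 4 did not pass (5 rose and 6 fell adjusted over the list alone), and the list was not called (camera, adjusted p 0.147). Fetal RNA-binding and heterochronic genes fell in 4 of 7 cases, Hmga2 51.5-fold (27.6-fold with the mean of its probe sets and 104-fold without _x_at and _s_at probe sets) and Igf2bp1 5.06-fold (4 adjusted over the list alone, adjusted p 0.000134, and adjusted p = 0.0767 with an estimated correlation).

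Retinoic acid genes also divided over the whole period. Aldh1a1, a retinaldehyde dehydrogenase, rose from 819 ± 183 to 4470 ± 347 (5.43-fold, adjusted p 5.95e-07), while Aldh1a2, another one, fell from 908 ± 250 to 224 ± 22.4 (3.79-fold lower, adjusted p 7.63e-06) and the binding protein Crabp2 fell 5.72-fold. Of 9 genes 2 rose, 3 fell and 4 did not pass (2 and 3 adjusted over the list alone, list adjusted p 0.761), and the list median of 0.12 and mean of -0.13 differed in sign. Crabp1 was among the 3 that fell, a call lost in 5 fits with an array left out and in 2 other settings. In the list named posterior Hox, 4 of 8 genes fell (Hoxa9, Hoxc6, Hoxc8 and Hoxc9), Hoxa9 from 206 ± 52.8 to 63.8 ± 16.4. Hoxc6 and Hoxc8 are central rather than posterior Hox genes. The list was shifted down (4 fell adjusted over the list alone, camera, adjusted p 0.0282, and adjusted p = 0.182 with an estimated correlation). Its call was also lost with the stricter filter and without E11.5 replicate 2. Among the 4, the call of Hoxc6 was lost in 8 fits with an array left out and 7 other settings, and that of Hoxc9 in 2 such fits. Of 3 adrenal-like genes, Cyp21a1, steroid 21-hydroxylase, rose 9.33-fold and Cyp11b1 1.92-fold, and Mc2r, the ACTH receptor, fell 2.63-fold, the last 2 calls each lost in 2 fits with an array left out (Mc2r log2 -1.40, and -2.01 and -0.78 without E18.5 replicates 1 and 2, 2 and 1 adjusted over the list alone, list adjusted p 0.273). In the mesonephros list Osr1 and Grhl2 rose, Cdh1 fell and 6 of 9 did not pass (2 and 1 adjusted over the list alone, list adjusted p 0.958), with a median of -0.02 and a mean of 0.24. Leaving out 1 array ended the call of Grhl2 in 7 fits and of Cdh1 in 2, and another probe set of Grhl2 went the opposite way (log2 -0.28 against 0.77). Heat shock and immediate early genes rose in 4 of 11 cases and Hsph1 fell (4 and 1 adjusted over the list alone, list adjusted p 0.0891). None of 3 neural, 3 skeletal muscle and 3 Y-linked or Xist genes passed (0 adjusted over each list alone, list adjusted p 0.786, 0.973 and 0.807), and the skeletal muscle list had a median of 0.02 against a camera direction of down. Xist, not tested, measured 39.1 ± 6.4 at E11.5 and 37.6 ± 2.2 at E18.5. Between them it measured 72.5 ± 39.4 at E12.5, 56.8 ± 6.4 at E14.5 and 38.2 ± 5.4 at E16.5. The E12.5 arrays read 100.3 (replicate 1) and 44.6 (replicate 2).

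Of the tests below, only the one on scanning day was fixed before its result was seen; the other 3 were chosen afterwards, and the limit used for the test without E14.5 replicate 1 was changed after its value was known.

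Embryonic globin signals fell between E14.5 and E16.5, with Hbb-y 43.6-fold lower. Less blood in the later preparations would lower the other red cell transcripts alike, but the median log2 change of Hbb-b2, an adult-type globin, and Alas2 was 0.981 (0.66 and 1.30, adjusted p 0.0796 and 0.00142). The red cell gene Slc4a1 pointed down without passing (-0.50, adjusted p 0.218, and -0.58 on another probe set), as did another probe set of Hbb-b2 (-0.29). The rise of Alas2 argues against less blood as the whole cause of a log2 change of -5.45 in Hbb-y, while a smaller loss of blood stays open. The replacement of yolk-sac red cells by those of the fetal liver is a candidate that was not tested, and cross-hybridisation at the Hbb-b2 probe sets stays open.

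Pluripotency genes fell between E14.5 and E16.5. A lower share of germ cells would lower other germ cell genes too, but the prospermatogonia and piRNA list had a median log2 change of 0.575, with 6 genes rising and 1 falling (6 and 2 adjusted over the list alone). That list was not called with an estimated correlation (camera, adjusted p = 0.252), with the stricter filter, or without _x_at and _s_at probe sets (median 0.346). Of the general germ cell genes, Ddx4 measured 722 ± 166 and 935 ± 151 (log2 0.37, adjusted p 0.37), while Dazl pointed down without passing (-0.69, adjusted p 0.0771, and -1.27 on another probe set). This argues against a lower share as the whole cause of a fall as large as that of Dppa3 (11.6-fold), but a smaller loss of germ cells may remain. A change of germ cell state with stage is a hypothesis that fits these values and was not tested further.

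In the fit to all arrays the step from E14.5 to E16.5 called more genes (1181) than any other successive step. Without E16.5 replicate 2 it called fewer than the earlier steps. Those steps kept all their arrays in that fit, so it cannot tell whether the order rests on single arrays. If the separate scanning day of E14.5 were the whole cause of the higher count, the genes called in this step should not move alike within another day. However, 92.0% of them had the same direction in E18.5 against E11.5 (exact binomial interval over genes, which are not independent, 90.3 to 93.4%), against 68.7% of all tested genes, and 61.8% were called there as well. A part played by scanning day stays open, as does one of the fluidics modules, which differed in both comparisons. Without E14.5 replicate 1 the step called 353 genes against 345 from E11.5 to E12.5, 190 from E12.5 to E14.5 and 0 from E16.5 to E18.5, so whether the higher count rests on that array, on E16.5 replicate 2 or on the stages could not be told.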
